A study of Homo sapiens with 16 samples.

How the data were processed

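ATAC-seq libraries were made with a commercial transposase kit and sequenced on an Illumina NextSeq, with single reads of 75 bp or pairs of 35 bp, per the labels' protocols. Bowtie2 2.3.4.1, SAMtools 1.9, deepTools 3.1.1 and MACS2 2.1.1 are named in the submitters' processing notes together with the human genome build hg19. The notes as used here give no role or order for them, and read shifting for the transposase, duplicate handling and caller settings are not given in the sources used here, except that the peak names of the single-end lists carry a tag for duplicate removal. The deposited lists have the 10 columns of the MACS2 narrowPeak layout, 1 list per library, so peaks were called per library and not on pooled replicates.

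Each deposited list gives, per peak, a fold enrichment ratio at the summit over the local background, the −log10 of the p-value and of the q-value, a score that is the whole part of 10 times −log10 q to within 1, and the summit position. These values are the authors' own. The lowest deposited −log10 q lay just above 4 in every list, so peaks with a q-value over 0.0001 are not listed. The score column was not used in any comparison, and fold and −log10 values served to describe, rank and filter peaks within a list.

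Peaks on chromosomes 1 to 22 and X were kept. The single-end lists also hold 8 to 10 mitochondrial peaks each and the paired-end lists 0, a difference in processing between the layouts. Peak names inside the lists follow different prefix styles: Pro, Sen replicates 1 and 2 and siFOXF1/2 share a style, and Sen replicates 3 and 4 and JUN-family knockdown share another. These were handled as separate processing sets, and within-set values stand beside the pooled ones. No label says that they were prepared apart.

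Peaks of a layout overlapping by at least 1 bp were merged into regions, 153040 for the paired-end and 103322 for the single-end libraries. A region was closed when every reference library and no library of the other group held a peak, opened in the reverse case, and kept when all libraries held one. The reference was Sen, or Pro for Sen against Pro. Closed and opened counts have no test and were set beside the counts from all other splits of the same libraries into groups of the same sizes, 14 splits for 2 against 4 and 4 for 2 against 2. Every other split mixes libraries of both groups on at least 1 side, which can lower its counts. Groups are too small for a p under 0.05. Peak numbers were compared by two-sided exact permutation tests. Each comparison names the 8 closed and 8 opened regions with the highest lowest −log10 q over the libraries that hold them, by the rule fixed before the data were examined, and the text gives the leading ones.

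Read totals are not part of the lists, so depth was recovered from them. MACS2 reports fold as (pileup + 1) / (background + 1) and a Poisson p-value, and these equations give the whole summit pileup and the local background of each peak. A whole pileup was found for 100% of peaks in every library, within 0.002 in −log10 p, widened in proportion where −log10 p exceeded 10. The 1st percentile of the local background served as genome-wide background coverage. The detection floor was the smallest pileup reaching the lowest listed p, 11 to 15 in paired-end and 5 to 7 in single-end libraries. The lowest pileup over background among libraries holding a region, divided by the highest floor over background among those lacking it, bounds the fold from below. A peak must also reach a minimum length, which this bound leaves out. Pileups were used for such bounds and as descriptions, and no count test was run. The recovery, the percentile, the bound and its size were chosen after seeing the data.

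Senescence-opened regions and overlaps between knockdowns were compared by Cochran-Mantel-Haenszel odds ratios over 10 bins of peak strength, the lowest −log10 q over the Sen libraries, and across layouts over bins of strength in each layout. Of the regions in both single-end Sen libraries 98.3% overlapped a paired-end region, and 88.6% overlapped one present in all paired-end Sen libraries. With split controls, 2 of the 4 Sen libraries defined opening and a region counted as closed when absent from the knockdown libraries. The plan also asked for a peak in the other 2, which would return the full set and was left out after seeing the data. Shares carry 95% Wilson intervals, which cover counting error over regions only.

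Alternatives fixed before the data were examined were a −log10 q of at least 5, lists of equal length, peaks covering at least 50% of a region, 500 bp windows on summits, leaving out each replicate, subsets of the Sen libraries and split controls. Alternatives added later were a −log10 q of at least 20, the depth bounds and overlaps within subsets of the Sen libraries. The 14 motif searches and 16 gene lists planned need an hg19 sequence and annotation, which were not used here because the gene table at hand is of GRCh38.p14, so regions are named by position and no gene is assigned.

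The steps were tested on simulated data. Whole pileups were recovered for 100% of 20000 simulated paired-end and 99.9% of 20000 single-end peaks. With real pileups as means, regions lost altogether were called closed in 100% of cases in each comparison, whereas a loss to 50% of the level was called in 14.7% of 191 regions for siFOXF1/2, 15.2% of 197 for JUN-family knockdown and 28.6% of 182 for p65. A loss to 25% of the level was called in 62.7%, 66.8% and 92.5%, and in 32.0% for Sen against Pro, so presence or absence misses most losses to 50% in each comparison and fewer of the deeper ones. Unchanged regions were called closed in 0.240% of 18717, 0.150% of 18715 and 0.702% of 17958. These rates hold for simulated draws around those means only. Real paired-end Sen libraries differed more without any knockdown. Of 88788 regions in Sen replicates 1 and 2, 5473 were absent from Sen replicates 3 and 4. In the reverse case 3987 of 86842 were absent. The simulated rates therefore cannot serve as false rates of the real closed calls. A planted odds ratio of 3 was estimated at 2.92. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.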

Results

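Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in IMR-90 ER:Ras cells. IMR-90 is an established human lung fibroblast line. This derivative carries an oncogenic Ras protein fused to an oestrogen receptor, and 6 days of 4-hydroxytamoxifen (4-OHT, 100 nM) drive the cells into oncogene-induced senescence. The series was designed around the transcription factors FOXF1 and FOXF2 and the acetyltransferases p300 and CBP in senescent cells. Peak lists of 16 libraries were analysed. The 10 paired-end libraries were 2 of proliferating cells (Pro), 4 of senescent cells with a control siRNA (Sen), 2 of senescent cells with siRNA against FOXF1/2 and 2 with knockdown of JUN-family members. The 6 single-end libraries were 2 each of Sen, of Sen with siRNA against p300/CBP and of Sen with siRNA against p65, the RELA subunit of NF-kB. The JUN libraries are titled cJUN/JUND but their treatment label also names JUNB, so "JUN-family knockdown" is used here. The Pro libraries carry the cell type label of senescent cells but no 4-OHT, and were taken as proliferating from their titles. Knockdown efficiency cannot be read from peak lists.

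The paired-end lists held between 60199 and 108323 peaks and the single-end lists between 17899 and 71181. Depth was read from the lists as the genome-wide background coverage, which ran from 1.74 to 3.08 in the paired-end and from 0.195 to 0.475 in the single-end libraries. A peak therefore had to reach 4.58 to 6.31 times the background to be listed in the first set, and 14.7 to 25.7 times in the second. Single-end lists can show the loss of strong peaks only, and were not compared directly with paired-end lists. Replicate lists overlapped with a Jaccard index, the shared share of all covered base pairs, of 0.735 for Pro, 0.718 for siFOXF1/2, 0.698 for JUN-family knockdown and a median of 0.675 (0.591 to 0.729, 6 pairs) for Sen. The single-end pairs reached 0.518 for Sen, 0.479 for sip300/CBP and 0.304 for sip65. Nothing in the labels says that replicates were separate cultures, so their spread cannot be called biological.

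**Figure D1:**
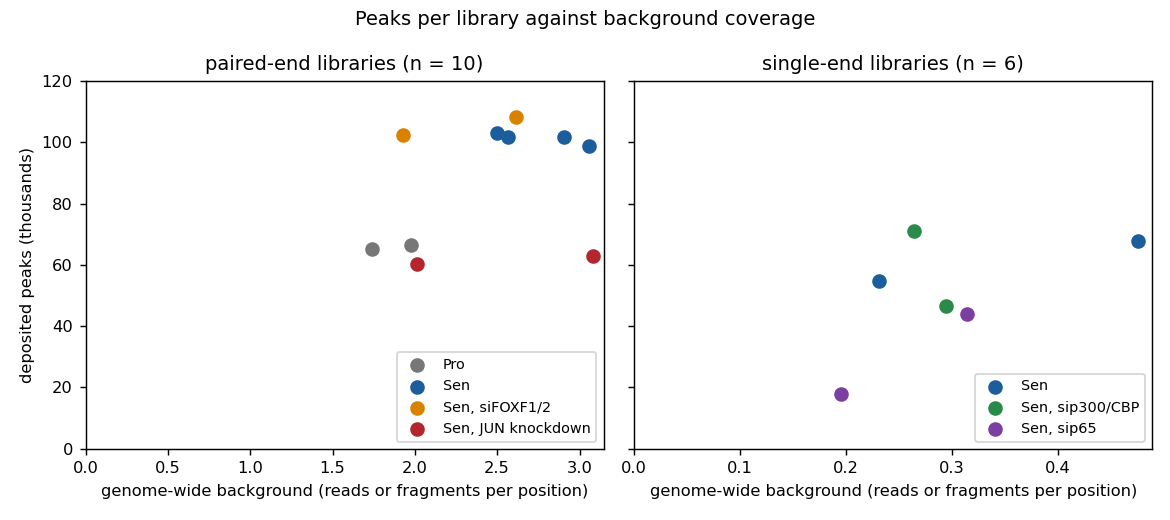
Deposited peaks per library (in units of 1000) against genome-wide background coverage (reads or fragments per position), 1 point per library, with paired-end libraries on the left and single-end libraries on the right. The 2 JUN-family knockdown libraries, at 3.08 and 2.01, hold 62787 and 60199 peaks, while the siFOXF1/2 library at 1.93 holds 102453.

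Entry into senescence was the first comparison. The Sen lists held more peaks than the Pro lists: 101280 ± 1800 (SD, n = 4) against 65844 ± 716 (SD, n = 2), a ratio of 1.54. They covered 50.8 ± 7.49 Mb against 31.1 ± 2.17 Mb. Neither value is scaled for depth, and background coverage in Sen was 1.48 times that in Pro. Of 153040 paired-end regions, 19961 carried a peak in all 4 Sen libraries and in neither Pro library and are called opened, 2270 were closed, with a peak in both Pro libraries and in no Sen library, and 49449 were kept in all 6. The opened regions made up 26.1% of the regions present in every Sen library. The closed regions made up 3.96% of those present in both Pro libraries.

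The strongest opened region lay on chromosome 6 at 155447903 to 155448631 (hg19), where the summit pileup was 77.6 ± 10.5 times the genome-wide background in Sen (SD, n = 4) and at least 4.89 times what could have stayed unlisted in Pro. Regions on chromosome 1 at 150868033 to 150868558 and on chromosome 5 at 452980 to 453679 reached 56.8 ± 6.04 and 74.5 ± 4.23 times the background in Sen (SD, n = 4), with lower bounds of 5.31 and 5.03 on the fold. Each of the 8 strongest opened regions kept its peak in both siFOXF1/2 and both JUN-family knockdown libraries. Among closed regions, chromosome 15 at 38828464 to 38829006 led with 70.1 ± 11.2 times the background in Pro (SD, n = 2) and a bound of 5.91. Both JUN-family knockdown libraries held a peak at 7 of the 8 strongest closed regions, and both siFOXF1/2 libraries at 3.

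A two-sided exact permutation test of the peak numbers gave p = 0.133, the smallest that 2 libraries against 4 can give. No other split of the 6 libraries opened more than 756 regions, whereas setting Sen replicates 1 and 2 apart closed 4627, more than the real groups did. The Pro lists were the shortest of the 6, which raises the opened count of the real groups whatever the cause. Lists cut to an equal length, the strongest 65281 peaks of each, gave 7842 closed and 7618 opened, counts that equal lengths even out by construction, and Pro had 1.86 ± 0.167 (SD, n = 2) against 2.76 ± 0.267 (SD, n = 4) of background coverage. Requiring a 2-fold bound left 6842 opened against 1540 closed, or 9615 against 1135 with libraries scaled on kept regions, and leaving out Pro replicate 1 or 2 gave 3808 or 3570 closed. Sen replicates 1 and 2, whose peak names share a prefix style with Pro, opened 29668 and closed 3674.

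**Figure D2:**
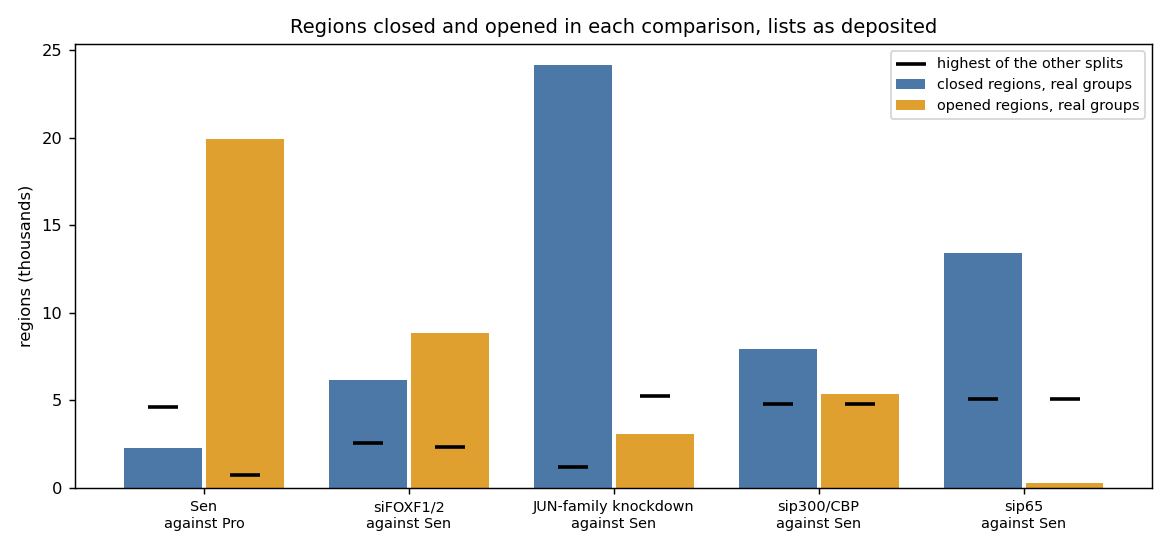
Regions closed and opened (in units of 1000) in each of the 5 comparisons, as bars for the real groups, with a black line at the highest count among the other splits of the same libraries. The JUN-family knockdown bar for closing stands at 24162 against at most 1177 in any other split, while its opening bar (3050) lies below the line at 5260. Every other split mixes libraries of both groups on a side, which can lower its counts.

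After knockdown of FOXF1/2, forkhead transcription factors of mesenchymal cells, the lists held about as many peaks as in Sen, in part at other regions. The libraries held 105388 ± 4151 peaks (SD, n = 2), 1.04 times the Sen mean. Peak numbers are not scaled for depth, and background coverage was 0.824 times that in Sen. Of the 76382 regions present in all 4 Sen libraries, 6186 (8.10%) closed, 65257 were kept, and 8824 regions with no Sen peak opened. Regions without any Pro peak made up 76.7% of the closed regions and 18.9% of the kept ones. Of the opened regions, 11.5% carried a peak in at least 1 Pro library, a share limited in advance by set sizes.

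The strongest closed region lay on chromosome 11 at 71902961 to 71903425, at 49.7 ± 6.36 times the background in Sen (SD, n = 4) and at least 4.57 times what could have stayed unlisted after knockdown. It was followed by chromosome 1 at 189988959 to 189989584, with 50.7 ± 6.75 (SD, n = 4) and a bound of 4.38, and chromosome 5 at 143626678 to 143627173, with 45.0 ± 4.96 (SD, n = 4) and a bound of 4.24. None of the 8 strongest closed regions had a Pro peak, and 4 of them kept a peak in both JUN-family knockdown libraries. The strongest opened region, chromosome 10 at 106006474 to 106007234, reached 67.7 ± 7.62 times the background after knockdown (SD, n = 2) with a bound of 6.15, and 7 of the 8 strongest opened regions had no Pro peak.

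The two-sided exact permutation p for peak numbers was 0.267, where the smallest possible, 0.133, could not have shown a difference. Both counts lay above every other split of the 6 libraries, where at most 2561 regions closed and 2314 opened, in each case with Sen replicates 3 and 4 set apart. Each such split mixes knockdown and Sen libraries on a side, which can lower its counts. The balance of closing and opening depended on scaling, with 1878 closed and 5283 opened at a 2-fold bound by background coverage and 3471 closed and 3060 opened when scaled on kept regions. Against Sen replicates 1 and 2, which share its prefix style, 9871 closed and 11172 opened, against replicates 3 and 4 10930 closed and 14513 opened, and without siFOXF1/2 replicate 2 9495 closed and 18066 opened. Without any knockdown, 5473 regions of Sen replicates 1 and 2 were absent from replicates 3 and 4, and 3987 in the reverse case.

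Knockdown of JUN-family members, subunits of the AP-1 transcription factor, removed a large part of the senescent peak set. The libraries held 61493 ± 1830 peaks (SD, n = 2), 0.607 times the Sen mean of 101280 ± 1800 (SD, n = 4). Of the 76382 regions in all Sen libraries, 24162 (31.6%) closed and 43819 were kept, while 3050 opened. The share closed ran from 71.3% in the weakest of 10 equal bins of Sen regions to 0.157% in the strongest. Such a gradient was seen in every comparison (23.7% to 0 for siFOXF1/2). Weak peaks lie nearer the detection floor, but how much of the gradient this gives was not tested.

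The strongest closed region, on chromosome 17 at 9292288 to 9292926, stood at 78.6 ± 9.44 times the background in Sen (SD, n = 4), at least 5.78 times what could have stayed unlisted, or 3.75 times when libraries were scaled on kept regions. Chromosome 6 at 160137293 to 160138385 and chromosome 15 at 31164397 to 31164967 followed, with 68.7 ± 10.0 and 61.9 ± 13.6 (SD, n = 4). Of the 8 strongest closed regions, 6 had a peak in both Pro libraries and 7 in both siFOXF1/2 libraries. The full set differed: of all 24162 closed regions, 61.0% had no Pro peak and 24.0% had one in both Pro libraries. Among kept regions these shares were 6.67% and 88.7%. The strongest opened region was on chromosome 1 at 80883371 to 80883688, at 33.6 ± 5.25 times the background (SD, n = 2) with a bound of 5.33, or 10.0 when scaled on kept regions. Opened regions held a peak in at least 1 Pro library in 32.2% of cases.

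The peak number difference gave a two-sided exact permutation p = 0.133, the smallest possible. The count of closed regions exceeded that of any other split (1177 at most), whereas the count of opened regions did not, since setting Sen replicates 1 and 2 apart gave 5260. The knockdown lists were the shortest of the 6, which raises the closed count of this split whatever the cause. At regions kept in all 6 libraries the summit pileup over background fell by 0.93 and 0.67 on the log2 scale in the knockdown libraries relative to the Sen mean, and the balance turned with how this was treated: 9265 closed and 1206 opened at a 2-fold bound scaled by background, but 1316 closed and 2974 opened when scaled on kept regions. Lists of equal length, which even out the counts by construction, gave 7183 closed and 7625 opened. Against Sen replicates 3 and 4, whose peak names share its prefix style, 30208 regions closed and 3300 opened, and without knockdown replicate 2 the opened regions numbered 5677. Without any knockdown, 3987 regions of Sen replicates 3 and 4 were absent from replicates 1 and 2.

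Knockdown of the coactivators p300 and CBP was compared with Sen in single-end libraries. The lists held 58881 ± 17396 peaks (SD, n = 2) against 61137 ± 9227 (SD, n = 2), a difference within the spread of replicates. Of 45431 regions in both Sen libraries 7904 (17.4%) closed and 29359 were kept, and 5333 opened. The strongest closed regions were on chromosome 13 at 100136767 to 100137031, at 67.5 ± 21.1 times the background in Sen (SD, n = 2) with a bound of 2.32, and on chromosome 7 at 134310330 to 134310606, at 72.9 ± 25.7 (SD, n = 2) with a bound of 2.06. Chromosome 15 at 83437517 to 83437686 led the opened regions, at 84.6 ± 8.85 times the background after knockdown (SD, n = 2) with a bound of 2.58.

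The two-sided exact permutation p for peak numbers was 1, with 0.333 the smallest that 2 libraries against 2 can give. Counts lay above the highest other split of the 4 libraries (4783), but only 37 closed and 85 opened regions reached a 2-fold bound, or 111 and 334 when scaled on kept regions, so few changes could be bounded at 2-fold at this depth. Leaving out 1 library moved the counts widely, to 19316 or 12370 closed without Sen replicate 1 or 2, 14661 closed without knockdown replicate 1, 9822 opened without Sen replicate 2 and 21328 opened without knockdown replicate 2.

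Knockdown of p65 gave the shortest lists. They held 30968 ± 18482 peaks (SD, n = 2), 0.507 times the Sen mean, and the 2 replicates differed, with 44037 and 17899 (ratios of 0.720 and 0.293 on their own). By presence or absence 13446 (29.6%) of the 45431 Sen regions closed, 15014 were kept and 250 opened. Chromosome 22 at 39034314 to 39034492 was the strongest closed region, at 75.1 ± 34.8 times the background in Sen (SD, n = 2), with a bound of only 1.64. A region on chromosome 6 at 156171507 to 156171733, at 68.7 ± 31.7 (SD, n = 2), was among the 8 strongest closed regions of both p65 and p300/CBP knockdown.

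No closed region reached a 2-fold bound scaled by background (12 when scaled on kept regions) and 1 opened region did (34), so no large set of losses could be bounded at this depth, and lists of equal length gave 1904 closed and 1752 opened by construction. The exact two-sided permutation p for peak numbers was 0.333, other splits closed up to 5077 and opened up to 5077, above the 250 opened here, and single libraries set the counts: 28702 or 20536 closed without Sen replicate 1 or 2, 29703 without p65 knockdown replicate 1, and 1182, 556 and 4928 opened without Sen replicate 2 and p65 knockdown replicates 1 and 2.

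Regions that opened in senescence were called closed upon every knockdown more often than regions shared by Pro and Sen. JUN-family knockdown closed 14734 (73.8%, 95% Wilson interval 73.2 to 74.4) of the 19961 senescence-opened regions and 11.7% (11.4 to 12.0) of the 49449 shared ones. FOXF1/2 knockdown closed 4747 (23.8%, 23.2 to 24.4) and 1.68% (1.57 to 1.80). At equal peak strength, over 10 bins, the odds ratios were 9.62 (95% interval 9.20 to 10.1) and 7.41 (6.85 to 8.01). Of the senescence-opened regions 3968 were closed by both knockdowns, 10766 by JUN-family knockdown only, 779 by FOXF1/2 knockdown only and 4448 by neither. At the 5971 senescence-opened regions that both single-end Sen libraries held, p300/CBP knockdown closed 33.4% against 12.1% of 31956 shared regions (odds ratio 2.95, 2.76 to 3.15) and p65 knockdown 52.5% against 17.7% (4.28, 4.02 to 4.55). These shares varied with the library: replicate 1 or 2 alone gave 38.6% against 14.6% or 49.9% against 25.5% for p300/CBP, and 54.8% against 19.2% or 84.5% against 56.1% for p65. Depth limits them too. Of all closed regions, 28.4% for p65 and 73.2% for p300/CBP lay above the detection floor scaled by background. These single-end odds ratios have no background without knockdown beside them.

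Part of this pattern also appeared without any knockdown. When Sen replicates 1 and 2 alone defined opening, 15.6% of 29668 opened and 0.747% of 50769 shared regions were absent from Sen replicates 3 and 4 without any knockdown (odds ratio 6.16, 5.52 to 6.89), beside 27.4% and 1.92% for FOXF1/2 (7.02, 6.54 to 7.54) and 81.1% and 13.3% for JUN-family knockdown (12.3, 11.8 to 12.9). With replicates 3 and 4 defining opening, the odds ratio was 2.59 (2.38 to 2.81) for absence from replicates 1 and 2, 5.89 (5.55 to 6.24) for FOXF1/2 and 8.34 (8.00 to 8.69) for JUN-family knockdown. Regions are not replicates, so these intervals describe the libraries at hand.

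**Figure D3:**
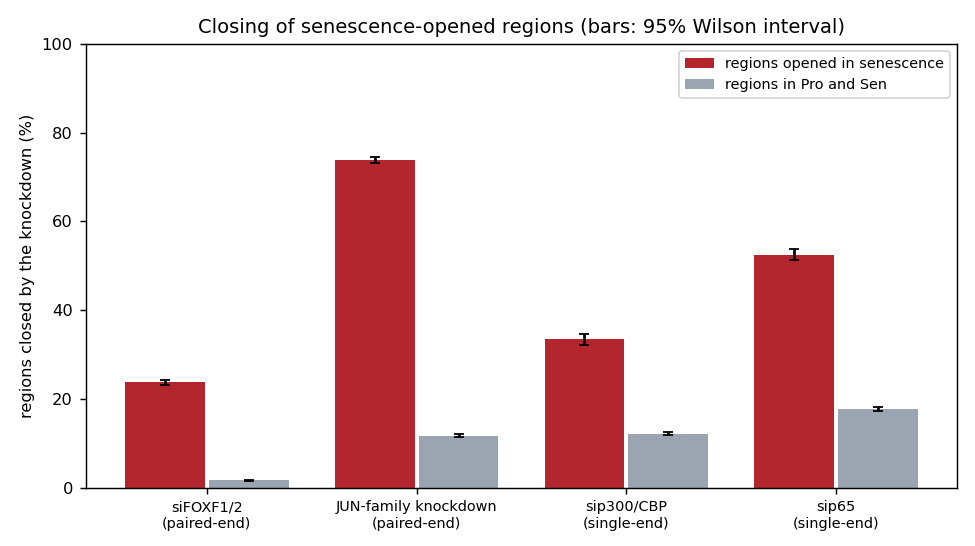
Percentage of regions closed by each knockdown among regions opened in senescence (red) and regions present in Pro and Sen (grey), with 95% Wilson intervals as error bars. The red bar is higher for each knockdown, from 23.8% against 1.68% for siFOXF1/2 to 73.8% against 11.7% for JUN-family knockdown.

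The closed regions of different knockdowns coincided to different degrees. Of the 6186 regions closed by FOXF1/2 knockdown, 4748 (76.8%) were also closed by JUN-family knockdown, where independent lists would share 1957. Across layouts, where no library is shared, 809 regions closed by FOXF1/2 knockdown lay in regions of all Sen libraries of both kinds. Of these, p300/CBP knockdown closed 524 (64.8%), with 130 for independent lists and an odds ratio of 5.81 (4.96 to 6.80) at equal strength. The 524 made up 8.11% of the 6465 regions that p300/CBP knockdown closed in this set. Knockdown of p65 closed 400 (49.4%) of the 809, with 195 for independent lists. At equal strength the odds ratio for p65 and FOXF1/2 was 0.932 (0.803 to 1.08), an interval apart from that of p300/CBP on the same 40242 regions. Depth limits the p65 calls more, with 28.4% of all its closed regions above the detection floor scaled by background against 73.2% for p300/CBP. How much of the contrast this gives was not tested. JUN-family closing overlapped with that by p300/CBP (2.20, 2.04 to 2.36) and by p65 (2.48, 2.32 to 2.65). Mere absence from Sen replicates 3 and 4, without any paired-end knockdown, gave 1.66 (1.27 to 2.17) with p300/CBP closing and 8.91 (5.70 to 13.9) with p65 closing, and absence from Sen replicates 1 and 2 gave 0.684 (0.556 to 0.842) and 0.663 (0.557 to 0.789). The p65 values therefore lay below the first of these backgrounds and above the second.

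FOXF1/2 and JUN-family knockdown share their Sen libraries, and their odds ratio of 3.36 (3.15 to 3.59) has to be read beside simulations of 1000 draws. Libraries that missed regions independently at their own rates shared 841 regions on average, and lists drawn at each knockdown's rate per strength bin shared 3427. Regions taken from Sen replicates 1 and 2 only gave 3.60 (3.39 to 3.82), between 1.53 (1.43 to 1.64) for FOXF1/2 knockdown and 11.4 (9.90 to 13.2) for JUN-family knockdown with mere absence from Sen replicates 3 and 4. Regions taken from replicates 3 and 4 gave 2.32 (2.21 to 2.43), between 5.30 (4.94 to 5.67) for FOXF1/2 knockdown and 0.792 (0.740 to 0.847) for JUN-family knockdown with absence from replicates 1 and 2. The overlap thus lay above 1 of the 2 backgrounds and below the other in each subset. For p300/CBP and p65, whose 2 Sen libraries cannot be split, 3863 regions closed in both beside 2339 for independent lists and 1574 and 3212 in the simulations (odds ratio 1.62, 1.54 to 1.71), and part of the excess may come from the shared controls.

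**Figure D4:**
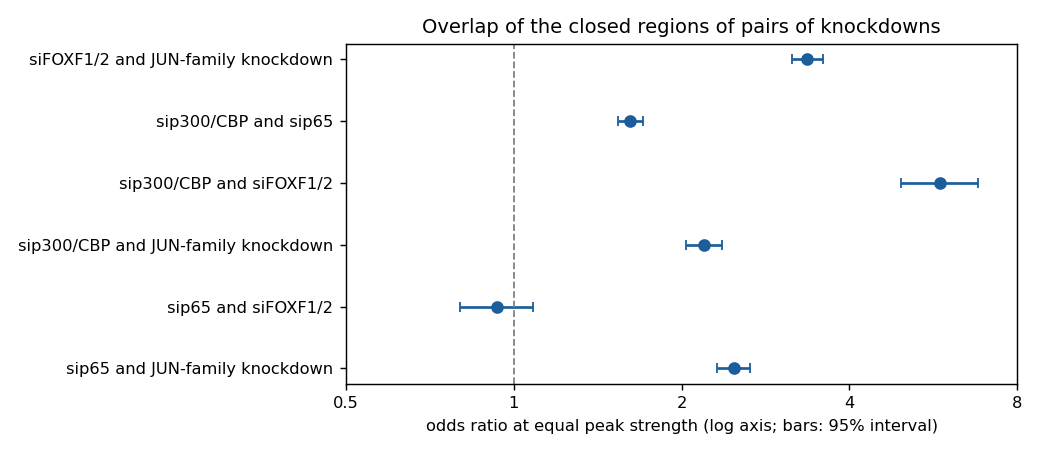
Odds ratio (log axis) that a region closed by the first knockdown of a pair was also closed by the second, at equal peak strength, with 95% intervals as bars and a dashed line at 1. The pair of sip300/CBP and siFOXF1/2 has the highest value, 5.81, and the pair of sip65 and siFOXF1/2, at 0.932, is the only interval to include 1.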

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

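Depth bounds, the −log10 q minimum of 20 and overlaps within subsets of Sen libraries were chosen after seeing the data, the other settings before. Of 189 settings over 25 results, 143 kept the value within its spread, within 1.5 times the count, or on the same side of 1 for an odds ratio, and 46 moved it, all of them counts of closed or opened regions. Odds ratios kept their side of 1, or their interval around 1 for p65 with siFOXF1/2, in every setting run. The −log10 q minimum of 5 removed under 1% of peaks in each list and tests little.

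Lists of equal length gave 7842 closed and 7618 opened for Sen against Pro, 7183 and 7625 for JUN-family knockdown and 1904 and 1752 for p65, an evening-out that follows from the equal lengths themselves. At a −log10 q of at least 20, JUN-family knockdown opened 1354. The replicate block, with Sen replicates 1 and 2 only, gave 3674 closed for Sen against Pro, 9871 closed for siFOXF1/2 and 5038 opened for JUN-family knockdown. With Sen replicates 3 and 4 only, JUN-family knockdown opened 3300, so the choice of Sen libraries and not their number alone moved that count, and the cause was not tested. For the single-end comparisons the block equals the reported count by construction. Shared numbers only name the samples. With the same replicates 3 and 4, siFOXF1/2 closed 10930 and opened 14513.

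A 2-fold bound scaled by background left 6842 opened for Sen against Pro, 1878 closed and 5283 opened for siFOXF1/2, 9265 and 1206 for JUN-family knockdown, 37 and 85 for p300/CBP and 0 and 1 for p65. Scaled on kept regions, it left 1135 closed and 9615 opened for Sen against Pro, 3471 and 3060 for siFOXF1/2, 1316 closed for JUN-family knockdown, 111 and 334 for p300/CBP and 12 and 34 for p65. These bounds drop regions by construction.

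Leaving out 1 library loosens the criterion and raised each count: closed regions to 2431 to 3808 for Sen against Pro, 6997 to 9495 for siFOXF1/2, 9315 to 19316 for p300/CBP and 14160 to 29703 for p65, and opened regions to 9409 to 18066 for siFOXF1/2, 3118 to 5677 for JUN-family knockdown, 7010 to 21328 for p300/CBP and 368 to 4928 for p65.

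Splitting the controls for the overlap of closed regions selects the same regions as the full set and tests nothing, so subsets of Sen were used. Motif and gene list alternatives were not run. Depth limits the closing by p65 knockdown most. Scaled by background, 28.4% of its closed regions lay above the detection floor, against 73.2% for p300/CBP and 97.4% for both siFOXF1/2 and JUN-family knockdown. Scaled on kept regions, the shares were 60.6% for p65, 91.4% for p300/CBP, 99.9% for siFOXF1/2 and 65.6% for JUN-family knockdown.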

Other observations

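The comparison by chromosome, the tests of depth, of kept-region signal for FOXF1/2 and of the detection floor for p65, the test of Pro peaks at opened regions with its bound, the test with opening defined by Sen replicates 3 and 4, the set of regions that decides whether the knockdowns open the same regions, and the demand that intervals lie apart for p300/CBP were chosen after the values were seen. So was the reading of split controls for JUN-family knockdown. The other tests were chosen before.

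Chromosome 19, the most gene-dense human chromosome, changed least. FOXF1/2 knockdown closed 3.57% of its 2294 Sen regions against 8.24% elsewhere (odds ratio 0.543 at equal strength, 0.432 to 0.683), p300/CBP knockdown 7.31% of 1573 against 17.8% (0.385, 0.315 to 0.469) and JUN-family knockdown 20.7% against 32.0% (0.733). Entry into senescence opened 14.9% of its Sen regions against 26.5% elsewhere (0.616, 0.542 to 0.700). The exception was opening by p65 knockdown, with 8 regions and an interval of 0.427 to 1.78.

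Part of the regions called closed in senescence held a peak after knockdown. Of the 2270, both JUN-family knockdown libraries held 654 (28.8%, 95% Wilson interval 27.0 to 30.7) and both siFOXF1/2 libraries 549 (24.2%, 22.5 to 26.0). Over all 28614 regions with no Sen peak JUN-family knockdown held 3050, a smaller share than its 654 of 2270, and siFOXF1/2 held 8824, a larger share than its 549 of 2270. Another split of the libraries closed 4627, and the wider set is chosen from the lists themselves, so reopening is not shown for siFOXF1/2 and stays untested for JUN-family knockdown. Both knockdowns held 142 of the 2270, inside the range of 122 to 204 over 1000 simulated draws that keep each knockdown's rate per strength bin, so at these regions the hypothesis that the knockdowns open the same regions found no support. Over all regions with no Sen peak, which were tested first, 413 opened with both, below the 1084 to 1293 of the draws, but that set holds only regions that some list holds, which lowers the overlap by construction.

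JUN-family knockdown closed more regions than it opened. Lower read depth is argued against: the shallowest paired-end library, Pro replicate 1, missed 31.2% of the regions in all Sen libraries and the shallowest senescent library, siFOXF1/2 replicate 2, missed 10.2%, while the knockdown libraries missed 37.0% and 37.3%, the first of them with the highest background coverage of all, 3.08. A lower signal over background, alike at every region, may account for part of it: at kept regions of equal Sen strength, the change in summit pileup at senescence-opened regions differed from that at shared regions by −0.13 and −0.15 on the log2 scale in the knockdown libraries. Without matching on strength the medians went the other way. They were −0.88 at senescence-opened against −0.92 at shared regions for knockdown replicate 1, and −0.60 against −0.66 for replicate 2. The comparison decides nothing. Only 2921 of 19961 senescence-opened and 38858 of 49449 shared regions kept their peaks, and the most reduced ones drop out. Closing itself, compared after the values were seen, cannot decide this either. The Sen libraries that served as background had no such drop, and a drop alike at every region was not simulated. Where Sen replicates 1 and 2 defined opening, the odds ratio at equal strength was 12.3 (11.8 to 12.9). Absence from replicates 3 and 4 gave 6.16 (5.52 to 6.89). With replicates 3 and 4 defining opening, the values were 8.34 (8.00 to 8.69) and 2.59 (2.38 to 2.81). How much a general drop added cannot be told, and AP-1 dependence of the sites was not tested.

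FOXF1/2 knockdown closed senescence-opened regions more often than shared regions. A lower signal over background is argued against, since the summit pileup over background at kept regions lay 0.25 and 0.30 above Sen on the log2 scale. Regions that passed the threshold by chance in Sen are argued against where Sen replicates 3 and 4 defined opening: the odds ratio for the knockdown was 2.28 times that for absence from Sen replicates 1 and 2, with intervals apart. They stay open where replicates 1 and 2 defined it, with 1.14 times, short of the 1.5 set beforehand. In that part, variation between cultures or processing sets may add to an effect of FOXF1/2, and these cannot be told apart.

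p65 knockdown closed more regions than it opened. Of its closed regions, 28.4% lay above the detection floor when scaled by background coverage and 60.6% when scaled on kept regions, so too few reads may account for much of the loss, and depth cannot be told apart from loss of NF-kB-dependent sites because the scalings disagree.

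A hypothesis that regions opened by siFOXF1/2 return to the proliferating pattern failed its test, but set sizes made that outcome likely in advance. The test therefore does not decide it. Of the 8824, 11.5% held a peak in either Pro library, and 13.7% of the strongest of 10 equal bins. How many peaks the shallower Pro lists missed was not measured. Set sizes limited this share in advance: 3808 regions held by Pro replicate 2 and 3570 held by replicate 1 lacked every Sen peak. The share therefore says that most opened regions lay outside the Pro lists, and not whether Pro regions reopened. The 1015 regions with a Pro peak were not tested further.

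That p300/CBP and FOXF1/2 knockdown close the same regions is a hypothesis that its test favoured for the regions closed by FOXF1/2 knockdown only. Only 809 of those lay in regions of all Sen libraries of both layouts. Knockdown of p300/CBP closed 524 (64.8%) of the 809, and the 524 made up 8.11% of its own 6465 closed regions in this set. The odds ratio of 5.81 between libraries of different layouts lay above the 1.66 (1.27 to 2.17) between p300/CBP closing and absence from Sen replicates 3 and 4, and remained 3.54 (2.59 to 4.84) with lists of equal length. These data may point to FOXF1/2-dependent sites that also need p300/CBP, though regions that vary between cultures for other reasons were not excluded. For JUN-family knockdown the odds ratio of 2.20 (2.04 to 2.36) lay above 1.66, which met the rule set beforehand, but the intervals overlapped, a demand added later. Absence from Sen replicates 1 and 2 gave 0.684 (0.556 to 0.842), below both knockdowns, so the question stayed open against the first background only.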
